A study of Mus musculus with 6 samples.

How the data were processed

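Total RNA from 6 samples of mouse brain cells (strain C57BL/6J) was profiled, 3 samples of GFP+ cortical neural progenitors and 3 of their RFP+ neuronal progeny, purified with a dual reporter by fluorescence-activated cell sorting. Per the labels, RNA was extracted with a Qiagen kit and labelled with biotin for Affymetrix whole-transcript arrays, 1 array per sample. The labels name the cortex for the GFP+ cells and only the brain, without a region, for the RFP+ cells, so a difference of region between the groups was not tested. The age of the animals and the promoters that drive the reporters were not given in the sources used here. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these samples.

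The values analysed were the intensity of each probe set as deposited by the authors, who named the Affymetrix Expression Console in their processing notes. Its version, the background correction, the normalization and the summarisation method were not given in the sources used here. The intensities lay on a linear scale with exact zeros (53 to 112 probe sets at 0 per array), and the array medians of 210.31 to 221.1 differed little. Highest intensities per array ran from 28533.44 to 34227.08. Fewer probe sets lay under an intensity of 16 in the RFP+ arrays (956 to 1346) than in the GFP+ arrays (1485 to 1559). Olfactory receptor genes, 1015 of them, guided the near-background level, with 95th percentiles of 201.515 to 224.128 per array.

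The value table held 35557 probe sets. Of these, 21789 carried 1 gene symbol, 1621 carried several, and 12147 were unnamed here. Of the single-gene probe sets 21698 matched by Entrez ID, and 0 symbols needed updating. For each of the 999 genes with more than 1 probe set, the one with the highest mean over the 6 arrays was kept, which left 19938 genes, all tested without a filter on dim genes. Named genes are identified by symbol, and no genome build was used.

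Intensities were tested as log2(intensity + 16) with limma 3.58.1 (lmFit and eBayes, two-sided, prior degrees of freedom 15.5) in R 4.3.3, GFP+ minus RFP+, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The median SE of a log2 difference was 0.215. The median log2 difference over all genes was -0.08. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The first principal component held 71.7% of the variance and parted the groups, and the second held 11.2%. Across genes, which are not independent replicates, Pearson correlations between arrays were 0.969 to 0.975 within GFP+, 0.978 to 0.984 within RFP+ and 0.897 to 0.917 between groups.

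The design, the tests, the alternatives and 41 gene lists were chosen before the data were examined. The lists came from general knowledge of cortical development, and 8 of them hold markers of other cell types. Of their 740 entries 695 were measured, and the others are not analysed here. Each list was tested with limma camera (correlation between genes preset to 0.01, two-sided, adjusted over the lists), with an estimated correlation and with fry, which tests whether a list's genes move one way on balance without comparing them with other genes. The genes named are the 10 with the largest difference each way among those past the threshold whose groups do not overlap. To these were added, for each list, the 3 passing members with the largest difference in its majority direction and the largest passing member the other way, and 9 genes fixed beforehand (Sox2, Pax6, Nes, Hes5, Eomes, Mki67, Dcx, Tubb3 and Tbr1).

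The sample titles carry replicate numbers, and a check of whether they pair samples was made by correlating, across genes, each array's deviation from its group mean. GFP+ and RFP+ arrays of the same number correlated at 0.204, 0.288 and 0.361. Those of different numbers correlated at -0.267 to 0.00422. Pairing by number would give such values, but deviations within a group sum to 0, so they are not independent. What the numbers stand for was not given in the sources used here. The test without pairing by number, fixed beforehand, was kept, and the paired fit was run as an alternative. Other alternatives were the pairing as a random effect, quantile normalization, median centring, leaving out the dimmest 30% or 50% of genes, the mean of a gene's probe sets, array weights, an intensity trend with robust moderation, log2(intensity + 1), all probe sets, a 2-fold size threshold, limma treat, lists without shared genes, and leaving out each array in turn. Leaving out both arrays numbered 1 was added after seeing the data.

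The pipeline was tested on simulated data with 50 genes changed at each size. It recovered 0 of 50 genes changed 1.5-fold, 17 of 50 at 2-fold, 46 of 50 at 4-fold and 50 of 50 at 8-fold, and called 3 of 19738 unchanged genes. All 6 shifted lists were recovered and 0 of 33 unshifted lists were called. Genes were drawn independently, so the list result does not cover correlated genes. Far fewer genes were changed than the 5973 that passed in the real data, which makes the adjusted threshold stricter. The recovered shares therefore do not give the recovery in the real data. Of the genes tested, 9 had passing probe sets that disagreed in direction: Aak1, Atp13a3, Ect2l, Hmcn1, Mecom, Nckap5, Shank2, Slitrk2 and Spef2.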

Results

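RNA from 2 populations of mouse brain cells (strain C57BL/6J) was measured on whole-transcript microarrays. Cortical neural progenitors carrying a green reporter (GFP+) and their neuronal progeny carrying a red reporter (RFP+) were separated by fluorescence-activated cell sorting, and each population was represented by 3 arrays. The comparison asks which genes distinguish progenitors from the neurons they produce. Expression of 19938 genes was tested. The median intensity of an array lay between 210.31 and 221.1, and the 1015 olfactory receptor genes, which served as a guide to the near-background level, had medians of 58.45 to 66.84 per array. All log2 differences below are GFP+ minus RFP+ on the log2(intensity + 16) scale with the standard error (SE), and all folds are on that scale, which understates the change of dim genes. The number of arrays, 3 in each group, limits the precision of every value.

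Progenitor genes were high in the GFP+ arrays and neuronal genes were high in the RFP+ arrays. Pax6, a transcription factor of cortical progenitors, was 5.03-fold higher in GFP+ progenitors (log2 difference 2.33 ± 0.20, adjusted p = 2.98e-08), with an intensity of 7499.8 ± 75.7 against 1487.9 ± 210.8 (SD, n = 3 arrays each). Sox2, a stem cell transcription factor, was 3.67-fold higher and Nes, which encodes the intermediate filament nestin, 5.23-fold higher. Mki67, a marker of dividing cells, was 5.44-fold higher, and Eomes, the transcription factor of intermediate progenitors, was 2.83-fold higher with a GFP+ intensity of 10675.7 ± 420.5 (SD, n = 3). Hes5, a Notch effector, was 1.73-fold higher (adjusted p = 0.00535). In RFP+ neurons Tbr1, a transcription factor of deep-layer neurons, was 4.45-fold higher (adjusted p = 2.12e-07). The microtubule genes Tubb3 and Dcx were 1.91-fold and 1.67-fold higher there, and both stayed bright in the progenitors, at 7010.8 ± 1558.3 and 4419.7 ± 519.3 (SD, n = 3). Hes5 and Dcx missed the threshold when both arrays numbered 1 were left out (adjusted p = 0.0815 and 0.0594), an alternative chosen after seeing the data. Their log2 differences there were 0.67 and -0.74. This alternative leaves 2 arrays per group, so a call lost under it does not by itself show dependence on the arrays numbered 1.

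**Figure D1:**
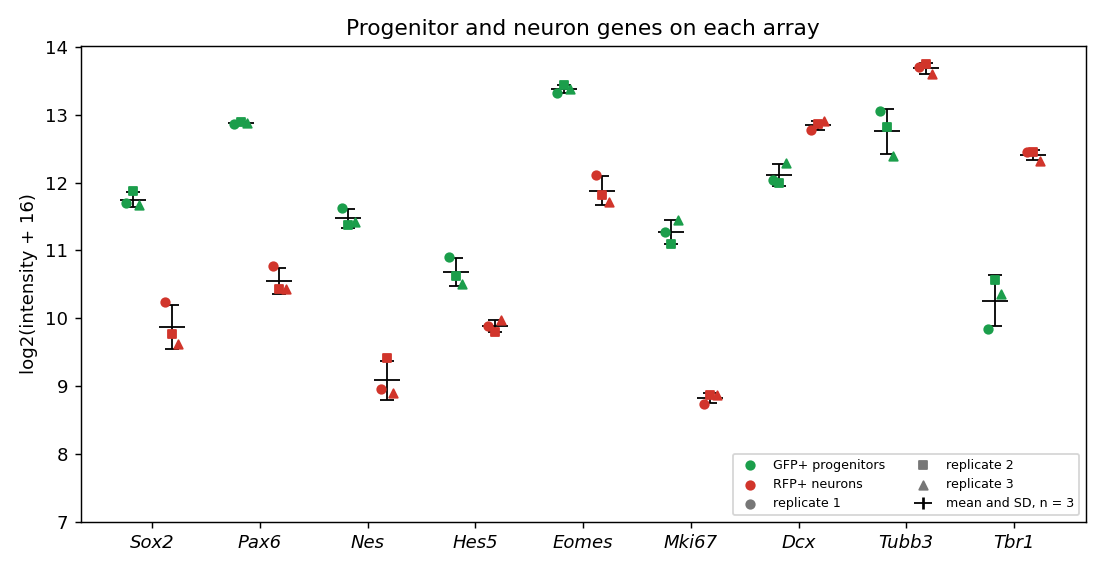
Level of 9 progenitor and neuron genes on each of the 6 arrays, as log2(intensity + 16). Green points are GFP+ progenitors, red points are RFP+ neurons, marker shapes give the replicate number, and black bars give the mean and SD (n = 3); for each gene the 3 arrays of one group lie on one side of the 3 of the other.

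In all, 5973 genes passed the threshold, 29.96% of those tested. Of these, 2740 were higher in GFP+ progenitors and 3233 were higher in RFP+ neurons. At least a 2-fold difference was seen for 1394 genes higher in GFP+ and 1191 higher in RFP+, and at least 4-fold for 402 and 198. The 10 genes with the largest rise in GFP+ progenitors were led by Vtn, a matrix glycoprotein gene that is also on the list of pericyte and mural markers (list median 2.53), at 17.7-fold (log2 difference 4.15 ± 0.21, adjusted p = 4.96e-10). They went on with Epas1, a hypoxia-inducible transcription factor (14.99-fold), the endothelin receptor gene Ednrb (14.8-fold), the metallothionein gene Mt2 (14.3-fold), the growth factor gene Igf2 (14.1-fold), the melanin synthesis gene Dct (13.6-fold), Olig2 (13.1-fold), the matrix protease gene Mmp9 (13.1-fold), Dlk1 (12.99-fold) and the proteoglycan gene Bgn (12.9-fold). The 10 genes with the largest difference the other way, all higher in RFP+ neurons, were 4922502B01Rik (13.1-fold), Bend6 (11.5-fold), the nuclear receptor gene Nr4a3 (10.6-fold), the Wnt agonist gene Rspo3 (10.4-fold), Hspa12a (10.1-fold), the dynein subunit gene Dync1i1 (log2 difference -3.32), the potassium channel genes Kcna1 (9.99-fold) and Kcnv1 (8.92-fold), Elmod1 (9.27-fold) and Sla (8.97-fold). In the group where they were lower, all 10 of the first set and 7 of the second had a mean intensity under the 95th percentile of the olfactory receptor genes (206.3 in RFP+, 211.3 in GFP+), so their folds and order depend on the offset of 16. The 3 arrays of one group did not overlap the 3 of the other for 5844 of the genes past the threshold. Over all genes tested 43.9% did not overlap, where chance gives 10%. With both arrays numbered 1 left out, 3848 genes passed, of which 1847 were higher in RFP+ neurons.

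**Figure D2:**
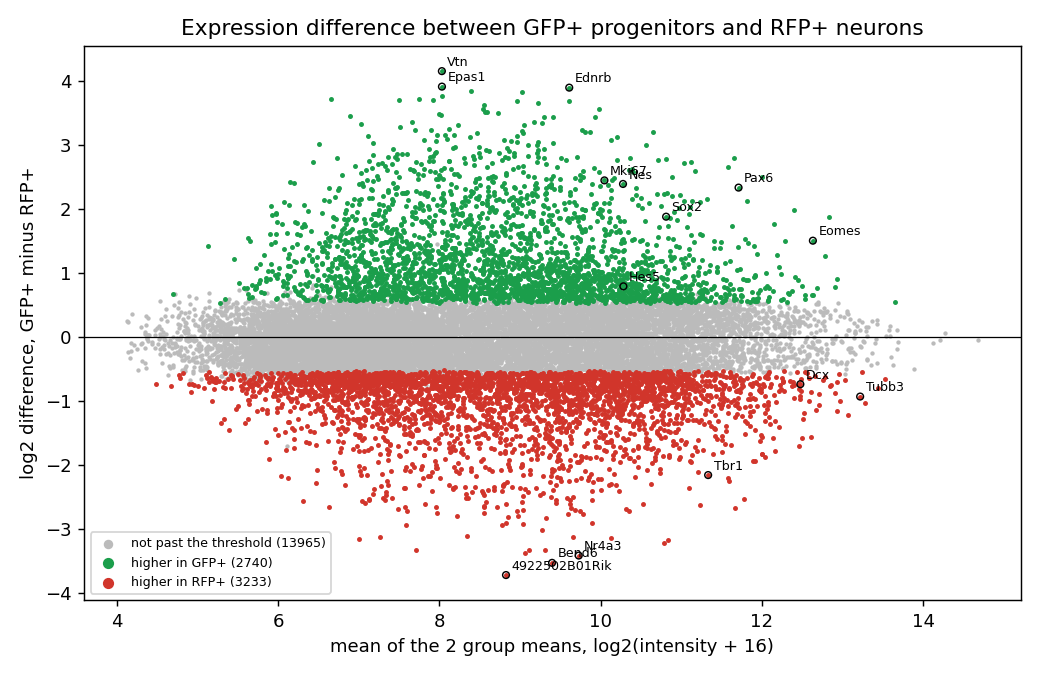
Log2 difference (GFP+ minus RFP+) of each tested gene against the mean of the 2 group means, both on the log2(intensity + 16) scale. Green points are the 2740 genes higher in GFP+ progenitors, red points the 3233 higher in RFP+ neurons and grey points the genes not past adjusted p 0.05; the circled genes are named in the text.

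The radial glia, intermediate progenitor and cell division lists were higher in GFP+ progenitors. Of 27 measured radial glia and neural stem cell genes, 25 were higher and 2 did not pass (26 higher and 1 lower when adjusted over the list alone), with a median log2 difference of 2.59 (camera adjusted p = 3.53e-27). Ednrb led this list, followed by Mfge8, a secreted glycoprotein gene (12.8-fold), and Pdpn, which encodes the membrane protein podoplanin (11.7-fold). Of 29 G2 and M phase genes, all 29 were higher, on the list alone as well (median 2.29, camera adjusted p = 1.22e-31). Examples were the kinetochore genes Cenpe (6.94-fold) and Bub1 (6.56-fold) and Birc5, which encodes survivin (5.71-fold). Of 28 S phase and DNA replication genes, 25 were higher and none lower (27 when adjusted over the list alone; median 1.47, camera adjusted p = 7.99e-19), among them the replicative helicase gene Mcm3 (5.55-fold), Uhrf1, which takes part in maintaining DNA methylation (5.48-fold), and the replication licensing gene Cdc6 (5.13-fold). These 3 lists also passed with an estimated correlation between genes (adjusted p = 0.0263, 0.0268 and 0.0204 with an estimated correlation, in the order given). For the other lists past the camera test the call was lost with an estimated correlation, and that adjusted p is given beside each. With 6 arrays that setting also tests on far fewer degrees of freedom, so a lost call does not by itself show correlated genes.

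Of 15 intermediate progenitor genes, 12 were higher in GFP+ progenitors and 1 lower (13 and 1 when adjusted over the list alone; median 1.502, camera adjusted p = 3.64e-09, adjusted p = 0.103 with an estimated correlation). The proneural gene Neurog1 was 7.002-fold higher, the antiproliferative gene Btg2 4.65-fold and Neurod4 4.41-fold. The member that went the other way was Neurod1, a transcription factor of neuronal differentiation, 3.34-fold higher in RFP+ neurons (adjusted p = 0.0950 with an intensity trend and robust moderation). Of 16 primary microcephaly and centrosome genes, 8 were higher and none lower (8 and 1 when adjusted over the list alone; median 0.79, camera adjusted p = 1.45e-06, adjusted p = 0.120 with an estimated correlation). They included the spindle gene Aspm (6.27-fold), Nde1 (6.01-fold) and the centriole duplication gene Stil (5.52-fold). Of 12 cell cycle inhibitor genes, 4 were higher and 1 lower, on the list alone as well (median 0.19, camera adjusted p = 0.0207, adjusted p = 0.140 with an estimated correlation). Btg2, the cyclin-dependent kinase inhibitor gene Cdkn2c (4.38-fold) and the growth arrest gene Gadd45g (4.26-fold) were higher in GFP+ progenitors, and Cdkn1c, another kinase inhibitor gene, was 2.05-fold higher in RFP+ neurons. The call of this list ended with the replicate number as a block (adjusted p = 0.0509) and without the genes it shares with other lists (adjusted p = 0.289, the highest over its camera alternatives, the lowest being 0.0116).

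**Figure D3:**
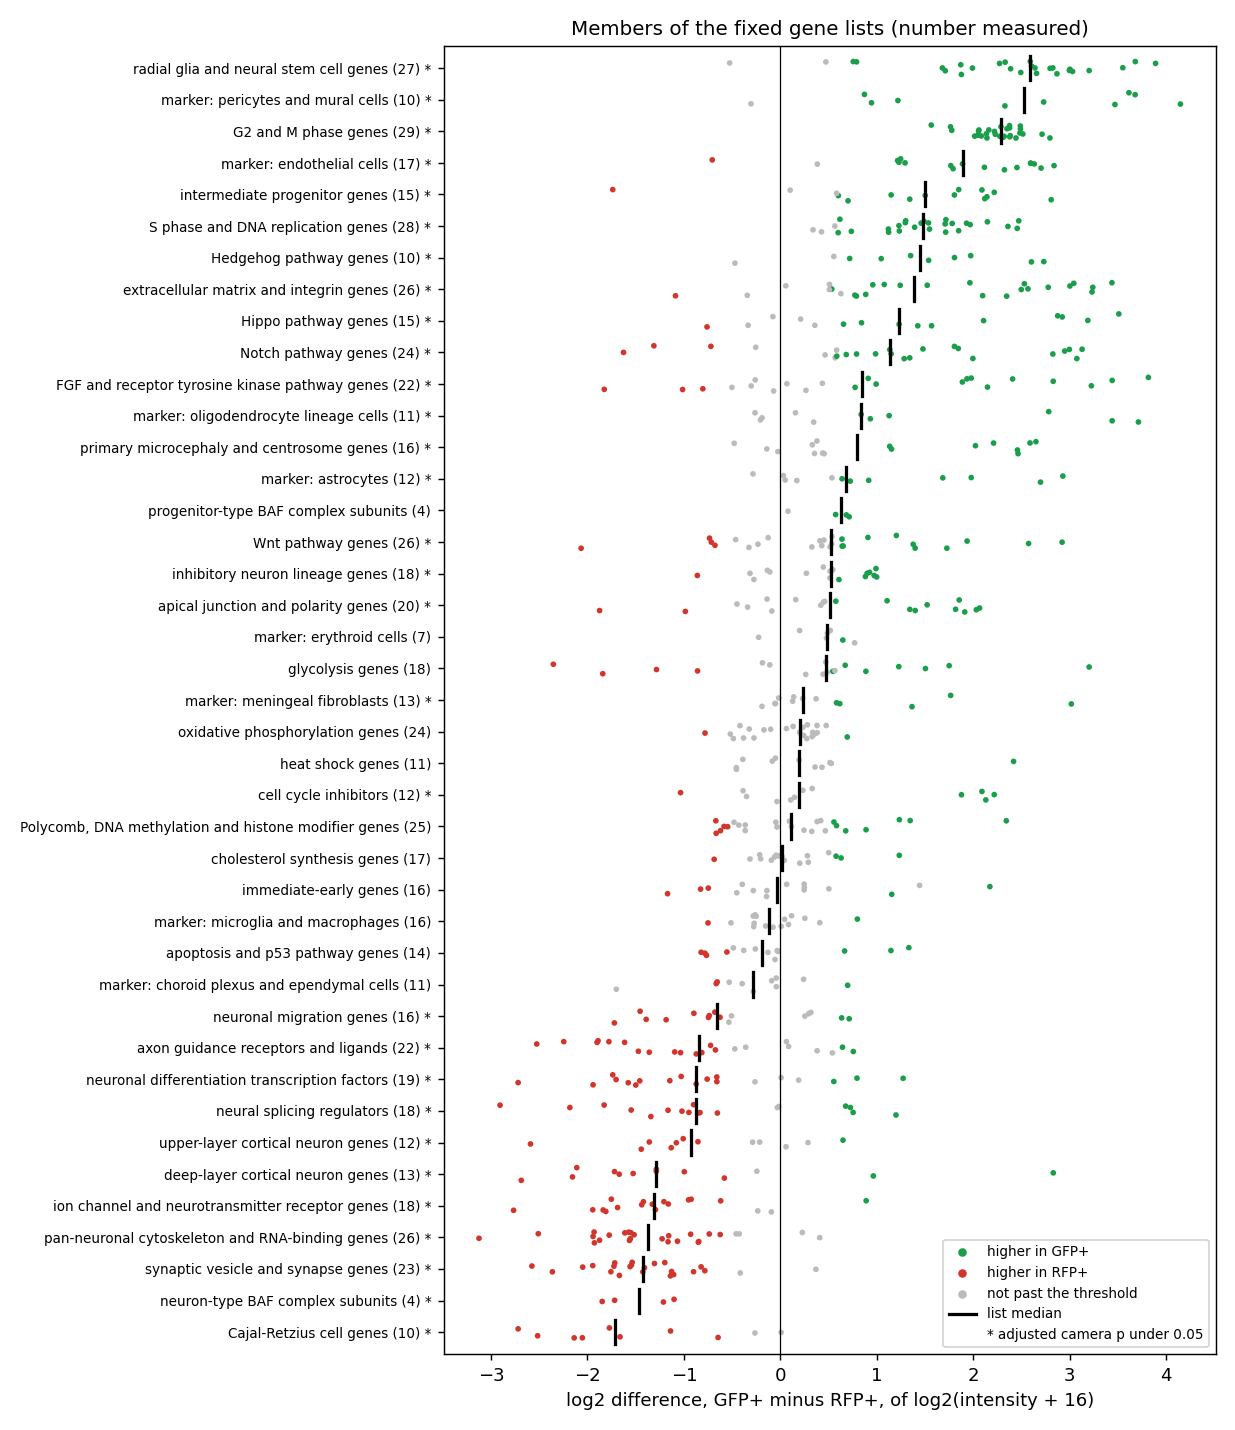
Log2 difference (GFP+ minus RFP+, of log2(intensity + 16)) of each measured member of the 41 gene lists, ordered by list median, with the number measured in brackets. Each point is a gene, green where higher in GFP+ progenitors, red where higher in RFP+ neurons and grey where not past the threshold; black bars are list medians and asterisks mark adjusted camera p under 0.05, which 30 lists reached.

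Genes of signalling pathways known from cortical progenitors were mostly higher in GFP+ arrays, as were markers of endothelial cells (median log2 difference 1.89) and of mural cells (2.53). Of 24 Notch pathway genes, 17 were higher and 3 lower (20 and 3 when adjusted over the list alone; median 1.14, camera adjusted p = 3.36e-09, adjusted p = 0.0921 with an estimated correlation). The glycosyltransferase gene Lfng was 8.74-fold higher and the receptor genes Notch2 and Notch1 8.42-fold and 7.98-fold, whereas Dtx1, a Deltex gene, was 3.09-fold higher in RFP+ neurons. Of 10 Hedgehog pathway genes, 8 were higher and none lower (9 when adjusted over the list alone; median 1.44, camera adjusted p = 2.78e-07, adjusted p = 0.103 with an estimated correlation), led by the co-receptor gene Gas1 (6.64-fold) and the transcription factor genes Gli3 (6.07-fold) and Gli2 (3.93-fold). Of 15 Hippo pathway genes, 10 were higher and 1 lower, on the list alone as well (median 1.23, camera adjusted p = 2.90e-07, adjusted p = 0.103 with an estimated correlation). Ajuba (11.4-fold), the YAP target Ccn1 (9.11-fold) and the coactivator gene Yap1 (7.58-fold) were higher in GFP+ progenitors, and Nf2 was 1.69-fold higher in RFP+ neurons. Of 22 FGF and receptor tyrosine kinase genes, 12 were higher and 3 lower, on the list alone as well (median 0.84, camera adjusted p = 1.90e-05, adjusted p = 0.120 with an estimated correlation). Igf2, the receptor genes Pdgfra (10.9-fold) and Erbb2 (9.34-fold) were the highest, and the phosphatase gene Dusp6 was 3.54-fold higher in RFP+ neurons. This call was lost without the dimmest 50% of genes (median 0.25, adjusted p = 0.0582, with 1.69e-06 to 0.120 over all camera alternatives of this list). Of 26 Wnt pathway genes, 11 were higher and 4 lower (13 and 4 when adjusted over the list alone; median 0.52, camera adjusted p = 9.03e-04, adjusted p = 0.152 with an estimated correlation). Tcf7l1 (7.57-fold), the receptor gene Fzd8 (5.95-fold) and Tcf7l2 (3.83-fold) were higher in GFP+ progenitors, and the ligand gene Wnt7b was 4.19-fold higher in RFP+ neurons.

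Many adhesion and matrix genes were also higher in GFP+ progenitors. Of 26 extracellular matrix and integrin genes, 20 were higher and 1 lower (23 and 1 when adjusted over the list alone; median 1.38, camera adjusted p = 9.94e-15, adjusted p = 0.103 with an estimated correlation). The matrix genes Sparc (10.8-fold), Nid1 (9.44-fold) and Lama4 (9.39-fold) were the highest, and the proteoglycan gene Vcan was 2.12-fold higher in RFP+ neurons. Beside these genes, markers of endothelial cells and of pericytes and mural cells were higher in the same arrays, with median log2 differences of 1.89 and 2.53. On GFP+ replicate 1 the matrix list lay -0.24 from the other GFP+ arrays (median log2, 16 of 26 members lowest there, Lama4 at -0.85 and Sparc at -0.54), and the endothelial list lay -1.34 from them. Of 20 apical junction and polarity genes, 10 were higher and 2 lower (11 and 2 when adjusted over the list alone; median 0.52, camera adjusted p = 3.75e-04, adjusted p = 0.123 with an estimated correlation). Alpha-catenin genes went opposite ways: Ctnna1 was 4.19-fold higher in GFP+ progenitors and Ctnna2, the neural form, 3.67-fold higher in RFP+ neurons. The polarity gene Crb2 (4.09-fold) and the scaffold gene Magi1 (3.76-fold) were higher in GFP+ progenitors.

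Neuronal structure and synapse genes were higher in RFP+ neurons. Of 26 pan-neuronal cytoskeleton and RNA-binding genes, 22 were higher in RFP+ neurons, none in GFP+, and 4 did not pass (23 when adjusted over the list alone; median -1.37, camera adjusted p = 2.50e-12, adjusted p = 0.103 with an estimated correlation). The neurofilament genes Nefl (8.72-fold) and Nefm (5.69-fold) and the transcription factor gene Myt1l (3.84-fold) differed most. Of 23 synaptic vesicle and synapse genes, 21 were higher in RFP+ neurons and none in GFP+, on the list alone as well (median -1.43, camera adjusted p = 4.15e-13, adjusted p = 0.103 with an estimated correlation). They included the postsynaptic scaffold gene Dlg2 (5.96-fold), Snap25, part of the vesicle fusion machinery (5.14-fold), and Slc17a7, a vesicular glutamate transporter gene (4.14-fold). Of 18 ion channel and neurotransmitter receptor genes, 15 were higher in RFP+ neurons and 1 in GFP+, on the list alone as well (median -1.31, camera adjusted p = 3.88e-08, adjusted p = 0.120 with an estimated correlation). The potassium channel gene Kcnq3 (6.80-fold), the sodium channel subunit gene Scn3b (3.85-fold) and the GABA receptor gene Gabra2 (3.57-fold) were higher in RFP+ neurons, and the kainate receptor gene Grik2 was 1.85-fold higher in GFP+ progenitors.

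Of 22 axon guidance genes, 14 were higher in RFP+ neurons and 2 in GFP+ progenitors (15 and 3 when adjusted over the list alone; median -0.84, camera adjusted p = 5.89e-05, adjusted p = 0.194 with an estimated correlation). The adhesion molecule gene Cntn2 (5.76-fold), the ephrin receptor gene Ephb1 (4.74-fold) and the semaphorin gene Sema3c (3.73-fold) were higher in RFP+ neurons, and another ephrin receptor gene, Epha4, was 1.69-fold higher in GFP+ progenitors (adjusted p = 0.0593 without both arrays numbered 1). Of 16 neuronal migration genes, 9 were higher in RFP+ neurons and 2 in GFP+ progenitors (11 and 2 when adjusted over the list alone; median -0.65, camera adjusted p = 0.0116, adjusted p = 0.181 with an estimated correlation). Dclk1 (3.30-fold), the Reelin pathway adaptor gene Dab1 (2.74-fold) and Cdk5r1 (2.62-fold) were higher in RFP+ neurons. The small GTPase gene Rnd3 was 1.64-fold higher in GFP+ progenitors, a call that ended when any 1 of 3 arrays (GFP+ replicate 3, RFP+ replicate 1 or RFP+ replicate 2) was left out (adjusted p up to 0.117). Without both arrays numbered 1, 10 axon guidance and 6 migration genes passed.

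Genes of cortical neuron subtypes were mostly higher in RFP+ neurons. Of 13 deep-layer genes, 10 were higher in RFP+ neurons and 2 in GFP+ progenitors, on the list alone as well (median -1.29, camera adjusted p = 1.55e-04, adjusted p = 0.241 with an estimated correlation). Ldb2 (6.44-fold), Tbr1 and Sox5 (4.32-fold) were higher in RFP+ neurons, and Etv1, an ETS transcription factor gene that is also a target of FGF signalling, was 7.11-fold higher in GFP+ progenitors. Of 12 upper-layer genes, 7 were higher in RFP+ neurons and 1 in GFP+ progenitors, on the list alone as well (median -0.93, camera adjusted p = 0.00584, adjusted p = 0.200 with an estimated correlation). The activin subunit gene Inhba (6.02-fold), Lmo4 (2.72-fold) and the netrin receptor gene Unc5d (2.56-fold) were higher in RFP+ neurons. Cux1 was 1.57-fold higher in GFP+ progenitors, and its call ended without GFP+ replicate 3, RFP+ replicate 1 or RFP+ replicate 2 (adjusted p up to 0.134). Of 10 Cajal-Retzius cell genes, which mark early-born neurons of the cortical surface, 8 were higher in RFP+ neurons and none in GFP+, on the list alone as well (median -1.72, camera adjusted p = 1.55e-06, adjusted p = 0.158 with an estimated correlation). They were led by Nhlh2 (6.58-fold), Trp73 (5.72-fold) and Reln (log2 difference -2.14), the last at an RFP+ intensity of 2412.2 ± 411.9 (SD, n = 3). Without the dimmest 30% of genes, a setting that takes dim members out before the test, 5 of the Cajal-Retzius genes passed. Of 19 neuronal differentiation transcription factor genes, 13 were higher in RFP+ neurons and 3 in GFP+ progenitors, on the list alone as well (median -0.87, camera adjusted p = 3.75e-04, adjusted p = 0.200 with an estimated correlation). Nhlh2, Myt1l and Neurod1 led them, and Ebf1 was 2.42-fold higher in GFP+ progenitors. Ebf1 was dim, at mean intensities of 195.1 in GFP+ and 68.4 in RFP+. Both lay under the 95th percentile of the olfactory receptor genes (211.3 and 206.3).

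Some inhibitory neuron lineage genes were higher in GFP+ progenitors. Of 18 measured, 7 were higher in GFP+ and 1 in RFP+, and 10 did not pass, on the list alone as well (median 0.52, camera adjusted p = 0.0155, adjusted p = 0.498 with an estimated correlation). The transcription factor genes Maf (1.997-fold), Dlx2 (1.99-fold) and Gsx2 (1.96-fold) were higher in GFP+ progenitors, and Npas1 was 1.82-fold higher in RFP+ neurons. Gsx2 was dim, at mean intensities of 119.6 in GFP+ and 53.4 in RFP+. Both lay under the 95th percentile of the olfactory receptor genes (211.3 and 206.3). The call rested on RFP+ replicate 3: without it the median was 0.24 and the adjusted p 0.267, 4 members passed, and Maf (adjusted p = 0.0514) and Dlx2 (adjusted p = 0.0924) did not. Npas1 lost its call without GFP+ replicate 3, RFP+ replicate 1 or RFP+ replicate 2 (adjusted p up to 0.128), and the list lost its call without the dimmest 30% of genes (adjusted p = 0.0624) and under fry (adjusted p = 0.240), with 5.03e-04 to 0.498 over all its camera alternatives.

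Neuron-type chromatin remodelling subunits and most neural splicing regulators were higher in RFP+ neurons. All 4 neuron-type subunits of the BAF chromatin remodelling complex were higher in RFP+ neurons, on the list alone as well (median -1.47, camera adjusted p = 3.28e-04, adjusted p = 0.103 with an estimated correlation), with Actl6b at 3.60-fold, Dpf3 at 3.29-fold and Dpf1 at 2.32-fold. Of the 4 progenitor-type subunits, 3 were higher in GFP+ progenitors and none lower, on the list alone as well: Actl6a (1.64-fold), Ss18 (1.61-fold) and Dpf2 (1.49-fold). That list did not pass (median 0.63, camera adjusted p = 0.0663). It passed with the replicate number as a block (adjusted p = 0.0438) and with log2(intensity + 1) (0.0489), with 0.0438 to 0.196 over all camera alternatives. It kept 1 passing member without RFP+ replicate 2 or RFP+ replicate 3. Dpf2 lost its call without any 1 of 5 arrays, all but GFP+ replicate 2 (adjusted p up to 0.108), and Ss18 without RFP+ replicate 2 or 3 (adjusted p up to 0.0551). Of 18 neural splicing regulator genes, 12 were higher in RFP+ neurons and 4 in GFP+ progenitors, on the list alone as well (median -0.88, camera adjusted p = 0.00209, adjusted p = 0.200 with an estimated correlation). Rbfox1 (7.49-fold), Khdrbs2 (4.54-fold) and Celf5 (3.55-fold) were higher in RFP+ neurons, and Ptbp1, a repressor of neuronal exons, was 2.30-fold higher in GFP+ progenitors. Of 25 Polycomb, DNA methylation and histone modifier genes, 7 were higher in GFP+ progenitors and 5 in RFP+ neurons, on the list alone as well, and the list did not pass (median 0.11, camera adjusted p = 0.193). Hmga2 (5.07-fold), the repressor gene Rest (2.54-fold) and the methyltransferase gene Dnmt3a (2.35-fold) were higher in GFP+ progenitors, and the demethylase gene Kdm6b was 1.59-fold higher in RFP+ neurons (adjusted p = 0.0956 without both arrays numbered 1). Without RFP+ replicate 1, 2 or 3, the passing members of that list numbered 6, 7 and 5.

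Metabolic and stress lists did not pass the camera test as sets. Of 18 glycolysis genes, 7 were higher in GFP+ progenitors and 4 in RFP+ neurons (11 and 4 when adjusted over the list alone; median 0.48, camera adjusted p = 0.0663, and 0.0438 with the replicate number as a block). The list passed without GFP+ replicate 3 (adjusted p = 0.0485) and without RFP+ replicate 2 (adjusted p = 0.0489), with 0.0438 to 0.393 over all camera alternatives. The isozyme genes differed: Aldoc (9.20-fold), Hk2 (3.36-fold) and the glucose transporter gene Slc2a1 (2.84-fold) were higher in GFP+ progenitors, and Eno2, the neuronal enolase gene, was 5.11-fold higher in RFP+ neurons. Of 17 cholesterol synthesis genes, 3 were higher in GFP+ progenitors and 1 in RFP+ neurons, on the list alone as well (median 0.02, camera adjusted p = 0.323). Idi1 was 2.35-fold and Insig1 1.55-fold higher in GFP+ progenitors, Dhcr7 1.49-fold, and Fdft1 was 1.61-fold higher in RFP+ neurons (adjusted p = 0.0593 without both arrays numbered 1). The call of Insig1 ended without any 1 of 4 arrays (adjusted p up to 0.0657) and that of Dhcr7 without any 1 of 5 (adjusted p up to 0.110), so that 2 members passed without RFP+ replicate 1, 2 or 3. Of 24 genes on the oxidative phosphorylation list, Sdhd (1.62-fold) was higher in GFP+ progenitors. Idh3a, a citric acid cycle gene on that list, was 1.72-fold higher in RFP+ neurons. No member passed when adjusted over the list alone (median 0.20, camera adjusted p = 0.537). Neither Sdhd nor Idh3a passed without GFP+ replicate 1 or RFP+ replicate 3, and only Idh3a without RFP+ replicate 2. With the replicate number as a block 5 members passed.

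Among 16 immediate-early genes, 2 were higher in GFP+ progenitors and 3 in RFP+ neurons, on the list alone as well. Jun was 4.51-fold higher in GFP+ progenitors, and Nr4a1 (2.25-fold), Dusp1 (1.77-fold) and Zfp36 (1.68-fold) were higher in RFP+ neurons. Fos, named after its values were seen, had an intensity of 1309.6 on GFP+ replicate 1 against 112.6 and 114.1 on the others, and of 999.0 on RFP+ replicate 1 against 91.4 and 105.8. The median of the immediate-early list (-0.04) and the direction of its test (toward GFP+, camera adjusted p = 0.834) differed in sign. Dusp1 lost its call without RFP+ replicate 1 (adjusted p = 0.0779), and Zfp36 without GFP+ replicate 3, RFP+ replicate 1 or RFP+ replicate 2 (adjusted p up to 0.136). Of 11 heat shock genes, only the co-chaperone gene Bag3 (5.34-fold) was higher in GFP+ progenitors, on the list alone as well (median 0.19, camera adjusted p = 0.319). With the replicate number as a block 4 of them passed, with it as a random effect 6, and 2 without GFP+ replicate 1 or GFP+ replicate 2. Of 14 apoptosis and p53 pathway genes, 3 were higher in GFP+ progenitors and 4 in RFP+ neurons, on the list alone as well (median -0.19, camera adjusted p = 0.673). The effector gene Bak1 was 2.52-fold higher in GFP+ progenitors, and Pmaip1 (1.77-fold, adjusted p = 0.0991 without both arrays numbered 1), Ccng1 (1.72-fold) and Bcl2l1 (1.70-fold) were higher in RFP+ neurons. Ccng1 lost its call without RFP+ replicate 1 (adjusted p = 0.0559).

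Genes on several lists of markers of other cell types were higher in GFP+ progenitors. The lists alone do not tell such cells from progenitors that express the same genes. Of 17 endothelial genes, 15 were higher in GFP+ and 1 in RFP+, on the list alone as well (median 1.89, camera adjusted p = 5.84e-10, adjusted p = 0.181 with an estimated correlation). Emcn (7.15-fold), Eng (6.51-fold) and Tie1 (6.20-fold) were higher in GFP+ arrays, at intensities of 384.9 ± 119.8, 395.1 ± 161.2 and 389.0 ± 205.1 (SD, n = 3), and the lactate transporter gene Slc16a1 was 1.63-fold higher in RFP+ neurons (adjusted p up to 0.0760 without GFP+ replicate 1, RFP+ replicate 2 or RFP+ replicate 3). Without the dimmest 30% of genes, a setting that takes dim members out before the test, 9 endothelial members passed. Of 10 pericyte and mural genes, 9 were higher in GFP+ and none lower, on the list alone as well (median 2.53, camera adjusted p = 2.85e-10, adjusted p = 0.103 with an estimated correlation). They were led by Vtn, Rgs5 (12.8-fold) and the receptor gene Pdgfrb (12.2-fold). Of 12 astrocyte genes, 7 were higher and none lower (8 when adjusted over the list alone; median 0.68, camera adjusted p = 7.31e-05, adjusted p = 0.120 with an estimated correlation). Gja1 (7.61-fold), Aldh1l1 (6.48-fold) and Fgfr3 (3.94-fold) were the highest, and 8 of the 12 lay above the 95th percentile of olfactory receptor genes in RFP+ neurons too. Of 11 oligodendrocyte lineage genes, 6 were higher and none lower, on the list alone as well (median 0.84, camera adjusted p = 4.82e-04, adjusted p = 0.204 with an estimated correlation), led by Olig2, Pdgfra and Olig1 (6.88-fold). Without the dimmest 30% of genes, which takes dim members out before the test, 3 of these passed.

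Of 13 meningeal fibroblast genes, 5 were higher in GFP+ progenitors and none lower, on the list alone as well (median 0.23, camera adjusted p = 0.0116, adjusted p = 0.120 with an estimated correlation). They were led by Foxc1 (8.09-fold), Col3a1 (3.40-fold) and Col1a2 (2.58-fold). This call was lost without the dimmest 30% of genes (adjusted p = 0.0501, 2 members, with 0.00511 to 0.120 over all camera alternatives), and 3 members passed without GFP+ replicate 2, RFP+ replicate 2 or RFP+ replicate 3. Of 16 microglia and macrophage genes, Laptm5 was 1.74-fold higher in GFP+ progenitors (adjusted p = 0.0532 without both arrays numbered 1) and Trem2 1.68-fold higher in RFP+ neurons, on the list alone as well (median -0.11, camera adjusted p = 0.834). Of 7 erythroid genes, Klf1 was 1.57-fold higher in GFP+ progenitors (none when adjusted over the list alone; median 0.49, camera adjusted p = 0.118). The erythroid list passed without GFP+ replicate 1 (adjusted p = 0.0131, the lowest over its camera alternatives, the highest being 0.419), when 3 members did, and no member passed without GFP+ replicate 2, RFP+ replicate 1 or RFP+ replicate 3. Of 11 choroid plexus and ependymal genes, Foxj1 (1.62-fold) was higher in GFP+ progenitors and Clic6 (1.59-fold) and Ccdc153 (1.57-fold) in RFP+ neurons, on the list alone as well (median -0.28, camera adjusted p = 0.427). None of these 3 passed without RFP+ replicate 3, and Clic6 and Ccdc153 also missed the threshold with quantile normalization (adjusted p = 0.0640 and 0.0594). In each group 2 of the 11 genes lay above the 95th percentile of olfactory receptor genes.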

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

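Leaving out both arrays numbered 1 was chosen after the result was seen, and the other alternatives were fixed beforehand. No named gene and no list median that passed its test reversed under any of them, while the near-0 medians of the immediate-early and cholesterol lists, which did not pass, changed sign under some. The balance of the counts did turn: more genes were higher in RFP+ neurons at first (3233 against 2740), and more were higher in GFP+ progenitors with a 2-fold requirement, under limma treat and with both arrays numbered 1 left out (2001 against 1847). Leaving out each array in turn gave 4508 to 5559 genes, with 2205 to 2546 higher in GFP+ progenitors and 2303 to 3041 higher in RFP+ neurons, and 29 to 31 gene lists past the camera test. Under the 10 other planned settings of the gene test the total lay within 1.5 times of 5973, from 4512 without the dimmest 50% of genes to 8178 with the pairing as a random effect. With quantile normalization 5643 of the genes were shared and 48.7% of those past were higher in GFP+ progenitors, and with median centring 41.6%.

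A stricter size requirement lowered the counts by its construction: at least 2-fold left 2585 genes (1394 higher in GFP+, 1191 higher in RFP+), and limma treat against 2-fold left 944 (601 and 343). With both arrays numbered 1 left out, which leaves 2 arrays per group, 3848 genes passed, 1847 of them higher in RFP+ neurons, and 3742 were among the 5973. That setting took the threshold from 22 named genes (highest adjusted p = 0.193). With an estimated correlation between genes, 3 lists passed. Lists whose estimated correlation lay under the preset 0.01 also lost their calls, the cell cycle inhibitors (0.00236) and the meningeal fibroblast genes (-0.0346). For these lists a higher correlation between genes cannot be the cause. Other lists that lost their calls had higher values, up to 0.587 for the endothelial genes, and the cause of the losses was not tested. The lowest correlation between arrays of 1 group fell from 0.969 to 0.943 without the dimmest 50% of genes, and the cause was not tested.

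With the replicate number as a block 7366 genes passed, 5947 of them among the 5973. The block ended the call of the cell cycle inhibitors (adjusted p = 0.0509), gave calls to the progenitor-type BAF subunits and glycolysis genes (0.0438 each), and moved the passing oxidative phosphorylation, heat shock and erythroid genes to 5, 4 and 3. It changed no other list call and took the threshold from no named gene. Of 158 named genes, 19 lost the threshold with an array left out (53 of 948 calls), and 6 under another planned setting: Clic6, Ccdc153, Neurod1, Npas1, Rnd3 and Klf1. Under fry 33 lists passed, among them the glycolysis (adjusted p = 0.0118), heat shock (0.0111), Polycomb (0.00246) and progenitor-type BAF (0.00149) lists. In simulated data 34% of 2-fold changes were recovered, a share not split by intensity. Far fewer genes were changed there than passed in the real data, so this share does not carry over to them. Differences of genes near the olfactory receptor level are compressed by the offset of 16, which limits their sizes.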

Other observations

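Gene families made from symbols, and a list of imprinted genes, were chosen after the data were seen, as were the tests of a fixed endothelial level, array background, shared handling, a single-array fault and carry-over of neurons. Noncoding transcripts that overlap or oppose a family gene, and the inhibitor genes Camk2n1 and Camk2n2, were left out. Of 89 potassium channel, auxiliary subunit and channel-interacting protein genes, 36 were higher in RFP+ neurons and 5 in GFP+ progenitors (median log2 difference -0.42, camera adjusted p = 7.38e-05, adjusted p = 0.178 with an estimated correlation). The 3 largest the other way were Kcnk5 (2.53), Kcnj10 (2.38) and Kcnj8 (2.33), the last also on the list of pericyte and mural markers. Of 10 calcium/calmodulin-dependent kinase and kinase-like genes, 7 were higher in RFP+ neurons, led by Camk2b (-2.83), Camkv (-2.79) and Camk4 (-2.75), while Camk2d (2.60) and Camk2a (1.66) were higher in GFP+ progenitors (family adjusted p = 0.0110, adjusted p = 0.284 with an estimated correlation). Of 19 Sox genes, 11 were higher in GFP+ progenitors, led by Sox21 (2.77), Sox8 (2.76) and Sox9 (2.64), and 4 were higher in RFP+ neurons: Sox5 (-2.11), Sox12 (-0.70), Sox4 (-0.66) and Sox11 (-0.66) (family adjusted p = 8.10e-05, adjusted p = 0.178 with an estimated correlation). The 11 include Sox18 (1.22) and Sox10 (1.13), which are on the endothelial and oligodendrocyte lineage lists.

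Of 38 kinesin genes, 16 were higher in GFP+ progenitors, led by the mitotic motor genes Kif4 (2.56), Kif11 (2.49) and Kif14 (2.46), and 7 in RFP+ neurons, including the axonal transport gene Kif5a (-1.60) and Kif26a (-1.10) (family adjusted p = 0.00251, adjusted p = 0.284 with an estimated correlation). The metallothionein genes Mt2 (3.84), Mt3 (3.20) and Mt1 (2.80) were all higher in GFP+ progenitors. Of 23 imprinted genes, 7 were higher in GFP+ progenitors, among them Igf2 (3.82), Dlk1 (3.70) and Grb10 (2.71), and 7 in RFP+ neurons, among them Rasgrf1 (-2.02) and Usp29 (-1.74) (adjusted p = 0.650). Of 287 microRNA-named probe sets, 31 were higher in RFP+ neurons, including Mir124a-3 (-1.84), and 6 in GFP+ progenitors (adjusted p = 0.202). These counts moved to 25 and 10 with quantile normalization and to 48 and 19 with the replicate block. Among olfactory receptor genes, the guide to background, 44 were higher in RFP+ and 14 in GFP+, and 23 and 27 with quantile normalization. Quantile normalization left the sign of the median of each of the 7 families as it was, olfactory receptor genes not being among them.

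Endothelial and mural markers were higher in GFP+ arrays, the brightest of the 2 fixed lists being Cldn5 (1265.7 against 289.8) and Rgs5 (1788.3 against 125.9). Sorting on the green reporter would remove cells that lack it. Whether vascular cells lack it is not known here, because its promoter was not given. A higher background on GFP+ arrays was argued against by the olfactory receptor genes, whose median log2 difference was -0.0578 (0.01 with quantile normalization). Its 95% interval of -0.09 to -0.04 came from resampling genes and does not measure the spread between arrays. The olfactory receptor medians were 58.45, 62.29 and 58.96 on GFP+ arrays and 66.84, 63.02 and 63.44 on RFP+ arrays. Progenitors that carry endothelial transcripts at a fixed level stay open: the endothelial list lay -1.34 from the other GFP+ arrays on replicate 1 (random lists -0.22 to 0.25, 15 of 17 members lowest there, radial glia list 0.01), but this is 1 array, and its list median of 7.76 (log2) was above the highest RFP+ value of 6.38. For mural transcripts the same value was 0.21, inside the range of random lists (-0.30 to 0.27), which leaves a fixed level in progenitors open. Vascular cells in the sort may contribute but cannot be told apart from other sources. Of 34 held-out vascular markers 47.1% (11 of 23 endothelial and 5 of 11 mural) were higher in GFP+ arrays, between the 60% and 20% set as bounds. That share was above the one over all genes, 2740 of 19938, and 1 marker, Rasip1, was lower (-0.76).

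Immediate-early genes were high on both arrays numbered 1: Fos lay 3.36 above the other GFP+ arrays and 3.15 above the other RFP+ arrays on the log2 scale. The smaller value of 3.15 compares with at most 0.18 between arrays 2 and 3 of a group. The pattern was picked as high on both arrays, so this value restates it and is no separate test of a single-array fault. General stress with a heat shock response was argued against only as a rise of the whole heat shock list. Its median deviation on array 1 was -0.00576 in GFP+ (interval -0.37 to 0.34) and -0.01 in RFP+ (-0.19 to 0.36). These intervals came from resampling the list's genes on 1 array per group and do not measure the spread between arrays. Handling shared by the samples of one number may be a source, with 10 of 16 members highest on array 1 in both groups. That count restates the observation that prompted it, so handling cannot be told apart from other differences between arrays of different numbers, which were not tested.

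Dcx and Tubb3 were less than 2-fold lower in GFP+ arrays, with GFP+ over RFP+ ratios of 0.601 and 0.533. Carry-over of average RFP+ cells as the whole cause was argued against, because the 5th percentile of that ratio over 4654 genes with an RFP+ intensity of at least 1000 was 0.336. Of the synaptic genes that bright, 16 of 16 lay below the ratio of Dcx, as did 17 of 23 pan-neuronal genes (lowest Dlg2 at 0.157 and Myt1l at 0.258). Signal so compressed that bright genes hardly differ was argued against, because 16.3% of the 129 genes as bright as Dcx (21) differed by over 2-fold. All 21 were lower in GFP+ arrays, but the 129 were picked on their RFP+ level, which favours that direction. Their share therefore cannot be set against the 12.97% of all genes, and partial compression stays open. No biological explanation was tested.

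The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 5973 genes and the highest of the others 0, and 1 split, the real one, gave as many. The real split and 3 of the others part all 3 pairs of arrays with the same number, and the remaining 6 part 1 pair.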
